A study of Mus musculus with 8 samples.

How the data were processed

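Bulk RNA sequencing libraries of the whole forebrain of 8 mice were compared, 4 from mice fed PLX3397 food and 4 from mice fed control food, grouped by the titles in the labels. The deposited table held whole-number counts per gene symbol, not normalized, with 53278 symbols in 8 columns, each column named after 1 sample. Per the submitters' processing notes, FastQC, MultiQC, STAR, DESeq2 and DESeq were used with the mm10 build; their versions and settings, the annotation release, the strand setting and the library kit are not given in the sources used here. Of the symbols, 49721 (93.3%) matched a gene name of GENCODE M21, which annotates the same build and gave the coordinates, biotypes and exon overlaps. Of the 78 genes named by rule, 26 share exon bases with another annotated gene, 21 of them on the opposite strand only, so their counts may include reads of the partner. Members of close gene families, such as the H2 and globin genes, are uncertain for the same reason.

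Total counts per mouse ranged from 48455538 to 68406688, of which the genes tested held over 99.9% in each library. Mitochondrial genes took between 4.76% and 6.34% of counts, and the 10 most abundant genes between 5.86% and 7.94%. A level of 1 CPM therefore corresponded to roughly 50 counts, and counting intervals cover counting error only. Chi-square tests of replicate pairs found no pair of libraries within sampling noise (at least 12.3 times the noise per gene, over genes with at least 10 counts), so each library was counted once.

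Groups, gene lists, tests, the rule for named genes and most alternatives were fixed before the data were examined. Genes were filtered with filterByExpr (20140 of 53278 kept), scaled with TMM and tested with edgeR 4.0.16 (glmQLFit and glmQLFTest, R 4.3.3), depleted against control, with no covariate, since the labels name no batch. Adjusted p-values are Benjamini-Hochberg values over all genes tested, with 0.05 as the threshold, and standard errors were derived from the fold change and its F statistic. The biological coefficient of variation was 16.1%. Levels are CPM on the TMM scale, and log2 CPM used a prior count of 2.

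The 32 gene lists covered microglia and other macrophages, purine handling and purinergic receptors, kinases and ligands around CSF1R, cytokines, interferon response, complement, the glial, vascular and neuronal cell types, immediate early genes, cholesterol synthesis, blood cells, the ventricles and meninges, and single brain regions. Lists were tested with camera (limma 3.58.1) on log2 CPM with a preset correlation of 0.01 and again with an estimated one, adjusted over the 32 lists, and members were counted over all genes and adjusted over each list alone. Each list's mean log2 CPM per mouse served as its score, compared by an exact two-sided permutation test over 70 splits. Members were matched by symbol, 3 of them through an older symbol. Genes were named by rule: Entpd1 and Csf1r; the 10 largest falls and up to 10 largest rises among genes past the threshold with a mean log2 CPM of at least 1 and no overlap between groups (7 rises qualified); up to 4 members per list past the threshold, or 2 with the smallest p where none passed; and all members of both purine lists that passed. A few other list members are named beside their list's count, chosen after their values were seen, as were the genes of the last part outside the lists.

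The steps were tested on simulated counts with 200 changed genes among 20140 drawn from the means and library sizes of these samples. The changed genes were picked only among genes with a mean of at least 1 CPM, so the recovery below does not cover weaker genes. For this comparison 26.0% of 1.35-fold changes, 54.0% of 1.5-fold, 88.0% of 2-fold and 98.8% of 4-fold changes were recovered over 5 runs. Of the calls 7.80% were false (above the nominal share). A moved list was called in 5 of 5 runs, and 0 of 155 unmoved lists were called. The simulated genes varied independently and the unmoved lists held random genes, so these runs cannot show false calls of lists whose members vary together.

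Fits planned beforehand used DESeq2 size factors or library size alone in place of TMM, no filter or a filter of 1 CPM in 4 samples, the replicate number as a block, DESeq2 1.42.0, limma-voom, an estimated correlation, a prior count of 0.5 and leaving out each mouse in turn. Those added after seeing the data were the striatum score as a covariate, the presence of at least 100 Hcrt counts as a block or as a split, 1 surrogate variable (sva 3.50.0), lists without microglia core members, and leaving out control mouse 1 and depleted mouse 1 together. Control mouse 1 had the lowest striatum score of its group, and depleted mouse 1 the lowest choroid plexus score of its group. Flags for single mice used Dixon's ratio with a critical value of 0.829 for 4 samples. All 35 splits of the 8 mice into groups of 4 were refitted. Lists of cell cycle, neuroblast, further striatal and cortical genes were written after the fixed lists had been tested. The table held 0 columns of other samples.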

Results

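Total RNA of the whole forebrain was sequenced in 8 male C57BL/6J mice aged 10 to 20 weeks. The 4 depleted mice ate food containing PLX3397, an inhibitor of the CSF1R kinase on which microglia depend for survival, for 9 days, and the 4 control mice ate control food. The count table held 53278 gene symbols, with 54410244, 48615169, 53168270 and 55007924 counts in control mice 1 to 4. Depleted mice 1 to 4 had 56813362, 49284874, 68406688 and 48455538 counts. The labels describe each sample as a separate mouse, so the errors below are spreads between mice (SD, n = 4 per group) unless a standard error of the model is named. The series title concerns microglia, the ectonucleotidase CD39 and the regulation of cerebral blood flow. Depleted and control forebrains were therefore compared over all genes, with lists for microglia, purine handling, blood vessels and other cell types.

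Microglial transcripts fell almost to the detection limit in the forebrain of every depleted mouse. Csf1r, the drug target (chromosome 18, 61100598 to 61132149, mm10), fell from 58.6 ± 5.49 to 1.22 ± 0.609 CPM (counts scaled to library size), a log2 fold change of -5.57 (SE 0.31, adjusted p = 1.01e-05 in edgeR's quasi-likelihood test). The purinergic receptor gene P2ry13 (log2 fold change -6.50, SE 0.46), the lectin gene Siglech (-6.33, SE 0.32), the fractalkine receptor gene Cx3cr1 (-6.07, SE 0.32) and the integrin gene Itgam (-6.07, SE 0.46) fell furthest among well-expressed genes. Fcrls (-5.81), Gpr34 (-5.60) and the complement subunit genes C1qc (-5.41), C1qa (-5.39) and C1qb (-5.29) fell nearly as far. The adjusted p of each of these genes was 1.10e-04 or less. Of the 35 members of the microglia core list, 34 fell, and the median log2 fold change was -4.79. When adjusted over the list alone 35 were lower, but Entpd1, with the largest p of the list, keeps its unadjusted p there.

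The falls within that list were not of one size. The homeostatic marker genes P2ry12 (-4.51, SE 0.24) and Tmem119 (-4.35, SE 0.16) left 4.40% and 4.90% of their control level, whereas the transcription factor gene Sall1 left 73.5% (-0.44, SE 0.08). The mean log2 CPM of the core list was 3.26 ± 0.13 in control and -0.80 ± 0.48 in depleted mice, a difference of -4.07 (exact two-sided permutation test over 70 splits, p = 0.0286, the smallest these groups allow). On that scale 5.97% of the control level was left, between 3.93% and 7.96% in single depleted mice, against 93.9% to 114% in single control mice. The list's fall passed with the preset correlation (camera, adjusted p = 1.10e-80) and with an estimated one (adjusted p = 0.0253), and in all 21 alternatives.

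**Figure D1:**
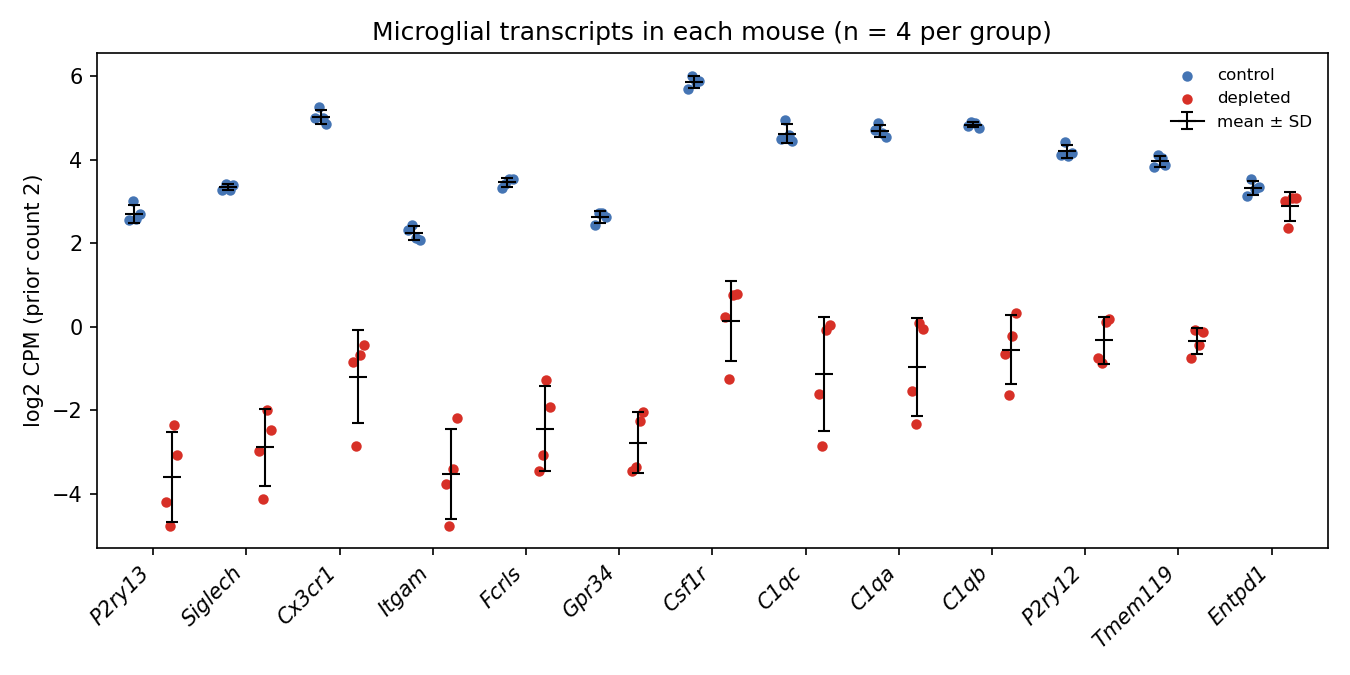
Expression of 13 microglial genes in each mouse, as log2 CPM with a prior count of 2, for control (blue) and depleted (red) mice, with bars for the mean and SD (n = 4 per group). The groups do not overlap for any gene shown; Entpd1, on the right, lies closest to its control level (74.4% left), and P2ry13, on the left, lies farthest from it (1.11% left).

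Across the 20140 genes tested, 223 fell and 11 rose at an adjusted p under 0.05. Of the genes that fell, 195 did so by more than 2-fold, 139 by more than 4-fold and 58 by more than 16-fold, and 173 belonged to none of the fixed lists. In each of the 234 genes the 4 depleted mice lay apart from the 4 control mice. These genes were chosen by a test of the same values, so their separation adds no support. Of all tested genes 5.77% were so separated, where chance gives 2.86%. DESeq2 called more genes, 351 lower and 128 higher (73.3% lower, against 95.3% in edgeR). The count of higher genes also depended on single mice: without depleted mouse 2 it was 243, beside 441 lower genes (64.5% lower), and without depleted mouse 3 it was 2.

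Some marker genes of border-associated macrophages, the perivascular and meningeal relatives of microglia, were lower as well. The scavenger receptor genes Stab1 (11.7 ± 1.89 to 2.18 ± 0.513 CPM, log2 fold change -2.42, SE 0.18) and Mrc1 (-2.42, SE 0.27) and the coagulation factor gene F13a1 (-2.19, SE 0.40) fell, at adjusted p of 5.60e-05, 0.00100 and 0.0285, but F13a1 passed in 11 of 20 alternatives (adjusted p up to 0.596). Mrc1 and F13a1 were weakly expressed, at 0.513 and 0.393 CPM in control mice, far below Stab1. Bulk counts do not show which cells carried these transcripts, so their falls do not measure a loss of border-associated macrophages. Cd163, another marker of these cells, stood at 1.18 (SE 0.45, adjusted p = 0.380). Of the 7 members with enough counts, 3 fell and none rose, and 4 were lower and 1 higher when adjusted over the list alone. The list passed with the preset correlation (median -1.63, adjusted p = 1.43e-05) and with an estimated one (adjusted p = 0.0446), but not with the stricter filter of 1 CPM in 4 samples, where the median of the members left was 0.017 (adjusted p = 0.303).

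Other immune lists differed in how many members fell. Of 18 complement and antigen presentation genes, 5 fell, among them C1qa, C1qb, C1qc and the anaphylatoxin receptor gene C3ar1 (-2.82, SE 0.27). Adjusted over the list alone, 11 were lower and 1 was higher (C4b, 0.57, SE 0.17). The list ranked lower (median -0.79, camera adjusted p = 1.03e-08; adjusted p = 0.170 with an estimated correlation). Without its microglia core members the list passed with the preset correlation (median -0.26, adjusted p = 1.49e-04), but not with an estimated one (adjusted p = 0.465). Of 12 cytokine and chemokine genes, Tgfb1 (4.53 ± 0.800 to 1.84 ± 0.312 CPM, -1.30, SE 0.17), Il1a (-2.42, SE 0.33) and the receptor gene Il10ra (-1.65, SE 0.31) fell, and 4 were lower when adjusted over the list alone. Il10ra passed in 11 of 21 alternatives, with a log2 fold change from -2.31 to -1.14 (adjusted p up to 0.251). The list ranked lower (median -0.11, adjusted p = 0.0338; adjusted p = 0.191 with an estimated correlation) and passed in 15 of 21 alternatives. Of 15 disease-associated microglia genes only the lysosomal Cd68 fell (-0.76, SE 0.12, passing in 15 of 21 alternatives), and 2 were lower when adjusted over the list alone. The list's median was 0.005, its mean -0.07 and its test pointed down (adjusted p = 0.692). Bulk counts do not show which cells carried these transcripts, so this list does not measure that microglial state. Of 23 reactive astrocyte genes only Cd14, which microglia also express, fell (-3.81, SE 0.28), and it was the 1 member lower when adjusted over the list alone (list median -0.10, adjusted p = 0.403).

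**Figure D2:**
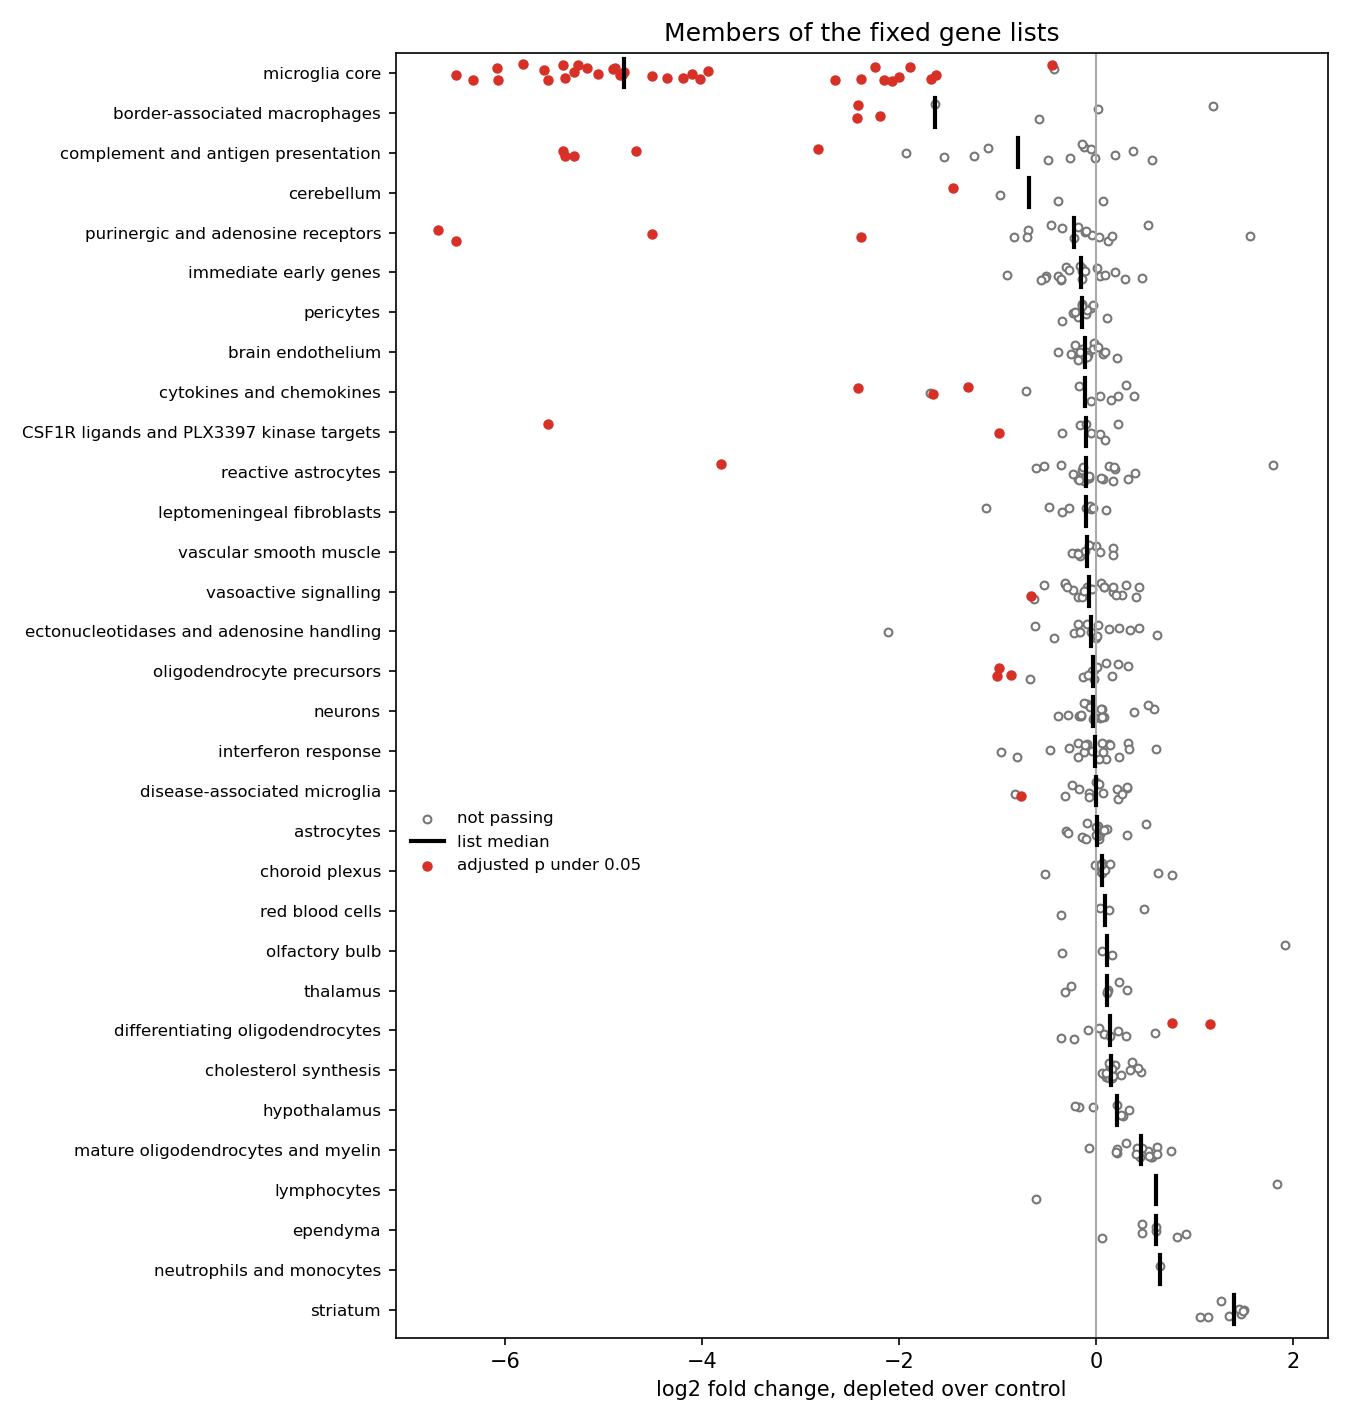
Log2 fold change, depleted over control, of each tested member of the 32 fixed gene lists, with 1 point per gene; filled red points have an adjusted p under 0.05, open points do not, and the black bar is the list median. The microglia core list has the lowest median (-4.79) and the striatum list the highest (1.40), although no striatum gene passed.

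Among purinergic and adenosine receptor genes, 4 of 19 fell: P2ry12, P2ry13, the UDP receptor gene P2ry6 (-2.38, SE 0.27) and the adenosine receptor gene Adora3. Adora3 had 1 count over the 4 depleted mice against 148 over the controls, which leaves 0.644% of the control level (95% exact counting interval 0.0162% to 3.64%); it shares exon bases with Tmigd3 on the same strand. P2rx7, the fifth member lower when adjusted over the list alone, stood at -0.35. The list passed with the preset correlation (median -0.22, adjusted p = 3.03e-05; adjusted p = 0.136 with an estimated correlation), but not without its microglia core members (median -0.14, adjusted p = 0.0554). Adora2a, a receptor gene abundant in the striatum, stood at 1.56 (adjusted p = 0.417) in libraries whose striatum score was 7.58 ± 0.89 in depleted and 6.16 ± 1.00 in control mice.

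Entpd1, which encodes CD39, the enzyme that hydrolyses extracellular ATP and ADP, did not pass the test over all genes. It lies on chromosome 19, 40612366 to 40741602 (mm10), and no other annotated gene shares its exon bases. Its level was 10.1 ± 1.16 CPM in control and 7.51 ± 1.59 CPM in depleted mice, a log2 fold change of -0.43 (SE 0.16, adjusted p = 0.380), or 25.6% lower. All 4 depleted mice lay below all 4 control mice (exact two-sided permutation test of log2 CPM, p = 0.0286, the smallest possible). Adjusted over the microglia core list alone, Entpd1 was lower (adjusted p = 0.0253). It had the largest p of that list, so this value equals its unadjusted edgeR p and carries no correction. Entpd1 did not pass when adjusted over the ectonucleotidase list alone (adjusted p = 0.0941). With the striatum score as a covariate its log2 fold change was -0.80 (SE 0.14, adjusted p = 0.0446), the only one of 21 alternatives that passed, in a range of adjusted p from 0.0446 to 0.991 and of log2 fold change from -0.80 to -0.20. Depleted mouse 2 was lowest, at 5.15 CPM against 8.02 to 8.47 CPM in the other depleted mice, and without it the log2 fold change was -0.28 (adjusted p = 0.267).

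None of the other ectonucleotidase and adenosine-handling genes passed. Of 17 tested members, 0 passed in edgeR, 0 in DESeq2, 0 in limma-voom and 0 when adjusted over the list alone, and 6 had an unadjusted p under 0.05 (list median -0.05, adjusted p = 0.773). The 5'-nucleotidase gene Nt5e, which makes adenosine from AMP, stood at 0.62 (SE 0.20, adjusted p = 0.303) and at 0.13 with the striatum score as a covariate. The nucleoside transporter gene Slc29a4 stood at -0.61 (SE 0.21, adjusted p = 0.344) and passed in 2 of 21 alternatives, at -0.89 without depleted mouse 2 (adjusted p = 0.00606) and at -0.94 in the 4 mice without Hcrt reads (adjusted p = 0.0316).

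**Figure D3:**
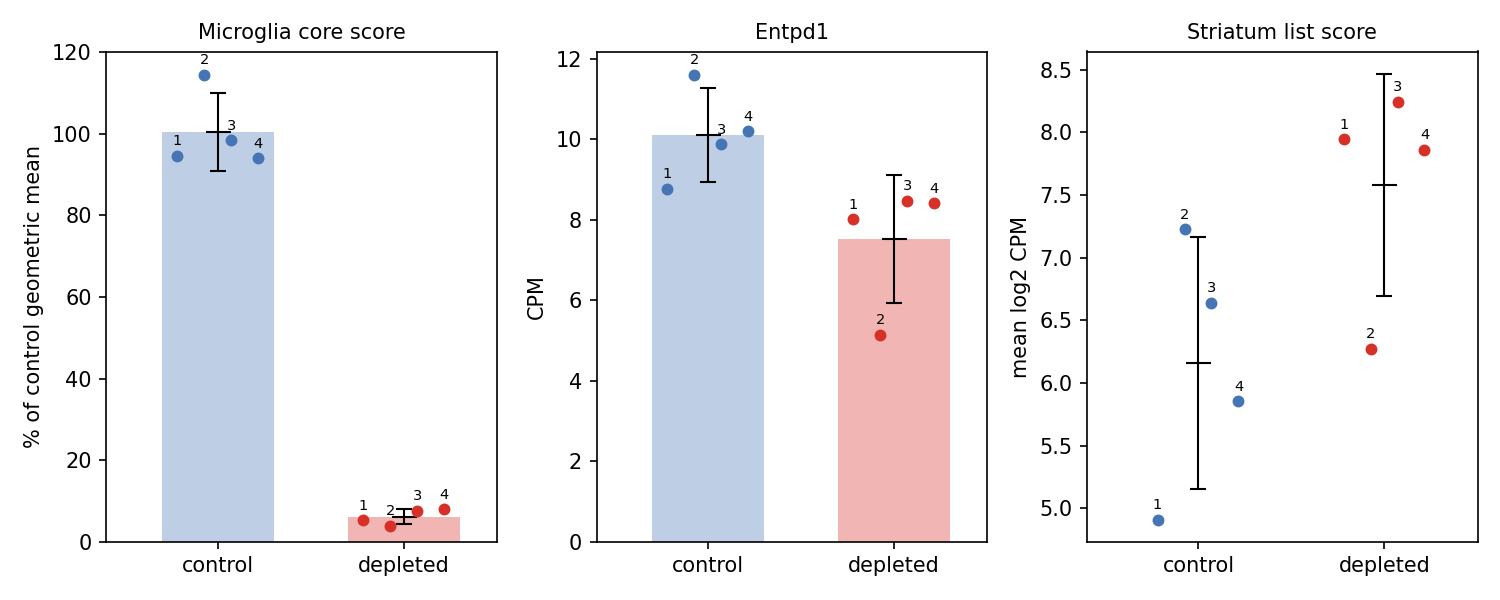
Microglia core score as a percentage of the control geometric mean (left), Entpd1 in CPM (middle) and striatum list score as mean log2 CPM (right) in each mouse, numbered as in the labels, with bars or marks for the group mean and SD (n = 4). The core score of the depleted mice lies between 3.93% and 7.96%, Entpd1 lies lower in each depleted mouse than in each control mouse, and the striatum scores of the groups overlap.

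Oligodendrocyte-lineage genes changed in both directions. Pdgfra, the growth factor receptor gene that marks precursors, fell from 42.9 ± 4.04 to 21.7 ± 3.87 CPM (-0.98, SE 0.13, adjusted p = 0.00304), and the precursor genes Cspg4 (-0.86, SE 0.08) and Matn4 (14.7 ± 1.24 to 7.32 ± 1.06 CPM, SE of the log2 fold change 0.12) fell with it, to 55.1% and 49.8% of the control level. Enpp6, a marker of newly forming oligodendrocytes, rose from 7.97 ± 0.988 to 17.8 ± 3.89 CPM (1.16, SE 0.16, adjusted p = 0.00419). Bmp4 (0.77, SE 0.14) and the oligodendrocyte transcription factor gene Zfp488 (0.71, SE 0.13) rose as well, as did the choline transporter gene Slc44a1 (0.44, SE 0.05) and the deacetylase gene Sirt2 (0.36, SE 0.07), both abundant in oligodendrocytes. The remaining rises among well-expressed genes were the long noncoding RNA Gm42047 (1.18, SE 0.23) and the cysteamine dioxygenase gene Ado (0.33, SE 0.06).

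Of the 14 precursor genes 3 fell and 3 were lower when adjusted over the list alone, while Olig1 and Olig2 both stood at -0.02. As a list the precursors ranked lower (median -0.03, adjusted p = 0.0368; adjusted p = 0.559 with an estimated correlation). Of 11 genes of differentiating oligodendrocytes 2 rose and 3 were higher when adjusted over the list alone, and the list ranked higher (median 0.14, adjusted p = 0.0113; adjusted p = 0.558 with an estimated correlation). Leaving out 1 mouse could end both calls: the precursor list passed in 15 of 21 alternatives (adjusted p up to 0.175 without 1 mouse, median from -0.21 to 0.08 over the alternatives) and the differentiating list in 17 (up to 0.135, median from 0.04 to 0.23). Of 16 mature oligodendrocyte and myelin genes, 15 had a positive fold change and 10 were higher when adjusted over the list alone, among them Cldn11 (0.62, SE 0.13, adjusted p = 0.0680 over all genes) and Mal (0.62, SE 0.13, adjusted p = 0.0739 over all genes). Over all genes 0 of these 16 passed in edgeR, 10 had an unadjusted p under 0.05, and 6 passed in DESeq2 and 0 in limma-voom. As a list they ranked higher (median 0.46, adjusted p = 4.38e-08, and adjusted p = 0.495 with an estimated correlation). With the striatum score as a covariate their median was 0.42, and 0 were higher when adjusted over the list alone. Pdgfra passed in 21 of 21 alternatives, Cspg4 and Matn4 in 20, and Enpp6 and Slc44a1 in 19, but Bmp4 passed in 11, Zfp488 in 10, Ado in 9, Gm42047 in 7 and Sirt2 in 6. Bmp4 lost its call without each of control mice 1, 2 and 4 and depleted mice 1 and 3 (adjusted p up to 0.128). The striatum score, higher in depleted mice, stood beside these rises. With it as a covariate Enpp6 (1.36) and Slc44a1 (0.40) still passed, but Bmp4 (0.91, adjusted p = 0.0633), Zfp488 (0.68, adjusted p = 0.330), Sirt2 (0.39, adjusted p = 0.224), Ado (0.30, adjusted p = 0.525) and Gm42047 (0.83, adjusted p = 0.799) did not.

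**Figure D4:**
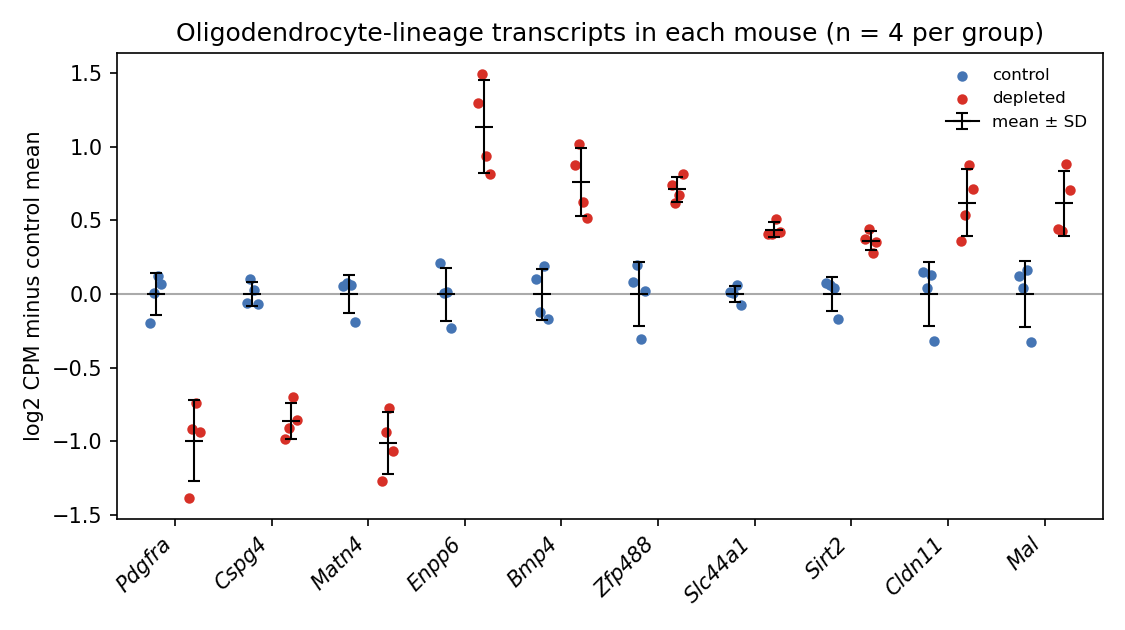
Oligodendrocyte-lineage genes in each mouse, as log2 CPM minus the control mean, for control (blue) and depleted (red) mice, with bars for the mean and SD (n = 4 per group). In depleted mice Pdgfra, Cspg4 and Matn4 lie below all controls, and Enpp6, Bmp4, Zfp488, Slc44a1, Sirt2, Cldn11 and Mal lie above all controls, although Cldn11 and Mal did not pass the test over all genes.

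A further list held CSF1R, kinases that PLX3397 may also inhibit and some ligands of these kinases. Its 9 tested genes were Csf1r, Csf1, Il34, Kit, Kitl, Flt3, Flt3l, Pdgfra and Pdgfrb. Only Csf1r and Pdgfra fell, over all genes and when adjusted over the list alone. The ligand genes Csf1 (0.22, adjusted p = 0.508) and Il34 (-0.05, adjusted p = 0.90) and the kinase genes Kit (-0.34, adjusted p = 0.573) and Flt3 (-0.16, adjusted p = 0.771) did not pass. The list ranked lower (median -0.10, adjusted p = 0.0275; adjusted p = 0.191 with an estimated correlation) and passed in 15 of 22 alternatives, but not without Csf1r, its microglia core member (adjusted p = 0.245).

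Cholesterol synthesis genes had fold changes of the same sign, but their list passed only with the preset correlation. All 20 had a positive fold change (median 0.15), with the sterol oxidase gene Msmo1 at 0.25 (SE 0.06, adjusted p = 0.104). Over all genes 0 passed in edgeR, 10 had an unadjusted p under 0.05, 3 passed in DESeq2 and 0 in limma-voom, and 5 were higher when adjusted over the list alone. The list ranked higher (adjusted p = 4.38e-08; adjusted p = 0.207 with an estimated correlation), and its score was higher in all 4 depleted than in all 4 control mice (difference 0.19, exact permutation p = 0.0286).

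The 3 lists of vessel wall genes did not pass. Brain endothelium (18 genes, median -0.11, adjusted p = 0.138), pericytes (11 genes, median -0.14, adjusted p = 0.0580) and vascular smooth muscle (10 genes, median -0.09, adjusted p = 0.765) had no gene past the threshold in edgeR, over all genes or when adjusted over the list alone. The endothelium list passed as lower in 4 of 21 alternatives, with the striatum score as a covariate (median -0.18, adjusted p = 0.0379), in the 4 mice with Hcrt reads and without control mouse 4 or depleted mouse 4, and the pericyte list passed in 3 (adjusted p from 0.0101). The largest shifts there were those of the lipid transporter gene Mfsd2a (-0.39, SE 0.10, adjusted p = 0.176) and the mitochondrial subunit gene Ndufa4l2 (-0.34, SE 0.19, adjusted p = 0.564), and Mylk, the myosin light chain kinase gene, stood at -0.24 (SE 0.12). Of 23 vasoactive signalling genes only the cyclooxygenase gene Ptgs1 fell, from 10.5 ± 1.60 to 6.63 ± 0.601 CPM (-0.66, SE 0.12, adjusted p = 0.0329), over all genes and when adjusted over the list alone (list median -0.07, adjusted p = 0.601). Ptgs1 is also expressed by microglia, and it passed in 12 of 21 alternatives.

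Lists of astrocyte, neuron, immediate early and interferon response genes did not pass. Astrocyte genes had a median of 0.01 with a test that pointed down (16 genes, adjusted p = 0.917), with Fgfr3 at -0.28 (SE 0.08, adjusted p = 0.243) and Gjb6 at -0.30. Neuron genes had a median of -0.02, a mean of 0.02 and a test that pointed up (18 genes, adjusted p = 0.917), with the GABA neuron genes Gad1 at 0.38 (SE 0.12, adjusted p = 0.309) and Slc32a1 at 0.53 (SE 0.21, adjusted p = 0.409). Immediate early genes (20 genes, median -0.15, adjusted p = 0.168) included Nr4a3 at -0.91 (SE 0.26, adjusted p = 0.230), and the list passed as lower in 4 of 21 alternatives (adjusted p from 0.0222). Interferon response genes (20 genes, median -0.01, adjusted p = 0.917) had 1 member lower when adjusted over the list alone, Trim30a (-0.80, SE 0.18, adjusted p = 0.0975 over all genes). Of the 113 genes in these 4 lists and the 3 vessel lists, 0 passed in edgeR and 0 in limma-voom, 11 had an unadjusted p under 0.05, and 3 passed in DESeq2 (Mfsd2a, Nr4a3 and Trim30a).

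Marker genes of single brain regions differed between libraries. All 8 striatum genes had a positive fold change (median 1.40), among them Pde10a (1.27, SE 0.42, adjusted p = 0.317). Over all genes 0 passed in edgeR, DESeq2 or limma-voom, 7 had an unadjusted p under 0.05, and 7 were higher when adjusted over the list alone. The list ranked higher with the preset correlation (adjusted p = 4.67e-05; adjusted p = 0.495 with an estimated correlation), while its score differed by 1.42 (exact permutation p = 0.0857) and ranged over 2.32 among the control mice. Ependyma genes had the same sign (7 genes, median 0.61, adjusted p = 0.0368; adjusted p = 0.610 with an estimated correlation), with 0 passing in edgeR, in DESeq2 or when adjusted over the list alone, 1 at an unadjusted p under 0.05, and a median of 0.14 once the striatum score was a covariate (adjusted p = 0.374). The ependyma list passed in 13 of 21 alternatives (adjusted p up to 0.185 without 1 mouse). Of 4 cerebellum genes Cbln3 fell (-1.45, SE 0.26, adjusted p = 0.0269), over all genes and when adjusted over the list alone, at about 1 CPM in the controls, and it passed in 10 of 20 alternatives. The cerebellum list (median -0.68, adjusted p = 0.0531) lay below all controls in all 4 depleted mice (exact permutation p = 0.0286) and passed as lower in 11 of 21 alternatives (adjusted p from 0.00164 to 0.980).

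The other region and blood lists did not pass: thalamus (7 genes, median 0.12, adjusted p = 0.688), hypothalamus (7 genes, median 0.21, adjusted p = 0.917), olfactory bulb (4 genes, median 0.11, adjusted p = 0.298), choroid plexus (11 genes, median 0.06, adjusted p = 0.917), and leptomeningeal fibroblasts (9 genes, median -0.10, adjusted p = 0.168). Nor did red blood cells (4 genes, median 0.09, adjusted p = 0.917), lymphocytes (2 genes, median 0.61, adjusted p = 0.991) and neutrophils and monocytes (1 gene, Hp, 0.65, adjusted p = 0.397). The choroid plexus list passed as higher in 3 of 21 alternatives (median 0.32 without depleted mouse 1, adjusted p = 0.00243) and the leptomeningeal list as lower in 3 (median -0.32 without depleted mouse 2, adjusted p = 0.00292). Of the 45 tested genes in these 8 lists 0 passed in edgeR and 0 in limma-voom, 4 had an unadjusted p under 0.05. In DESeq2 1 passed, the olfactory bulb gene Eomes (1.92, SE 0.62, adjusted p = 0.303 in edgeR), which was also the only one higher when adjusted over its list alone. The hypothalamic neuropeptide gene Hcrt had 1578, 1628, 1249 and 2081 counts in control mice 2 and 3 and depleted mice 2 and 3, and 12 or fewer in the other 4 mice, so both groups held libraries with and without it. Of the 32 lists, 7 ranked lower and 5 higher with the preset correlation and 2 passed with an estimated correlation, while exact permutation of the list scores could not decide after adjustment, since 8 lists lay at its smallest possible p of 0.0286, which gave them an adjusted p of 0.114.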

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

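The outlying values here come from a scan set beforehand, and the tests of striatal content and of Entpd1 were chosen after the results were seen, except that the second striatal list and the overlap check were written before their values were known.

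Single mice stood apart from the other 3 of their group in 15 of 220 sets of 4 values, where chance gives about 1 in 20, or 11. Depleted mouse 2 accounted for 5 of them, including log2 CPM of 2.37 for Entpd1 (others 3.01 to 3.09), -2.85 for Cx3cr1 (others -0.83 to -0.44), 6.93 for Fgfr3 and 2.30 for Cd4. In the other depleted mice, Slc44a1 was 6.84 in mouse 3, Adora3 was -4.12 in mouse 4, the only one with a count, and the pericyte list score was 2.97 in mouse 1 (others 3.14 to 3.17). Among controls, Stab1 was 3.86 in mouse 2, Hp, the only tested member of the neutrophil and monocyte list and so also its score, was -1.92 in mouse 2, Cbln3 was -0.38 in mouse 1, and in mouse 4 Sirt2 was 7.02, Matn4 was 3.69 and the score of the CSF1R ligand and kinase list was 4.88.

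Depleted mouse 2 had the lowest striatum score of its group, 6.27 against 7.86 to 8.24, and its score lay within the control range of 4.91 to 7.23. A candidate explanation for the striatal difference is an unequal share of striatal tissue in the dissected forebrains. Deviations from the group means of the striatum score and of a second striatal list correlated across the 8 libraries (Pearson r = 0.994, Spearman rho = 1, exact permutation p = 0.00174 for each over 576 pairings, the smallest they can give), and r was 0.991 without control mouse 1 and depleted mouse 2, which lay farthest from the median. A cortex list gave r = -0.46 with the striatum score. A response of striatal genes to the depletion stays open, since the group difference of 1.42 gave an exact permutation p = 0.0857 and the control mice alone ranged over 2.32, so these 8 libraries do not separate the explanations for the group difference.

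Entpd1 kept 74.4% of its control level where the microglia core list kept 5.97%, and a transcript with sources outside microglia would behave so. A fall as large as that of the core list, hidden under a higher striatal share, is argued against by the covariate fit. With the striatum score as a covariate Entpd1 stood at -0.80 (SE 0.14), far above the core median of -5.06 in the same fit. Without the covariate it stood at -0.43, so a smaller hidden part is not argued against. Surviving microglia with their usual Entpd1 level are argued against by the core level, at most 7.96% in any depleted mouse, although a higher Entpd1 level per surviving cell was not tested. Reads of an overlapping gene are argued against by 0 other annotated genes sharing its exon bases. Endothelial cells, which also carry CD39, may supply the remainder: their list had a median of -0.110. Deviations from the group means of Entpd1 and the endothelium score gave a Pearson r of 0.29 (exact permutation p = 0.495) and a Spearman rho of 0.43 (p = 0.333) over 8 libraries, and r = 0.69 without depleted mouse 2 and control mouse 1, which leaves this open.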

How the results depend on the processing

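The striatum, Hcrt, surrogate variable, core-free list and joint omission fits were chosen after the data were seen; the others were planned. Against 11 higher genes, the counts were 25 with no filter, 6 with 1 CPM in 4 samples, 4 with the replicate block, 128 with DESeq2, 2 with the striatum covariate, 0 and 128 in the 4 mice with and the 4 without Hcrt reads, 37 with 1 surrogate variable, and 4 without control mouse 1 and depleted mouse 1. Against 223 lower genes, they were 351 with DESeq2 and 66 in the mice with Hcrt reads, where 4 mice were fitted. The 4 mice without Hcrt reads gave 184 lower genes (59.0% lower).

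Leaving out 1 mouse gave 178 to 441 lower and 2 to 243 higher genes and 3 to 6 higher lists. Without depleted mouse 2 they were 441 and 243. Higher genes numbered 5, 7 and 6 without control mouse 1, 3 or 4, and 2 and 7 without depleted mouse 3 or 4. Without control mouse 4, 3 lists were higher.

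Of 5 higher lists, 3 passed with the striatum covariate, 3 without Hcrt reads and 0 with an estimated correlation, which kept 2 of 7 lower lists. Entpd1 passed only with the striatum covariate, at -0.80. Medians turned negative and their lists passed as lower for lymphocytes with no filter (-0.66, adjusted p = 0.0327, more members tested) and for neutrophils and monocytes in the mice with Hcrt reads (-1.09, adjusted p = 0.00399). For the striatum list with its own covariate only the direction of the test turned, at a median of 0.025, by construction. Where no reason is given, the cause was not tested.

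Replicate numbers do not pair the mice: residuals of same-numbered mice correlated at -0.22, -0.17, 0.37 and -0.01, and 1 of 4 depleted mice correlated best with its own number. With the block the core score difference stayed -4.07, at p = 0.125, the smallest an exact sign-flip test of 4 differences allows.

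The median log2 fold change of all genes stayed within 0.02 of 0 in each setting. Of the other single-gene results 1448 kept their call and sign, 9 kept their call with another sign, 123 lost it, 26 gained it and 0 reversed; of list results 536 kept both, 68 kept the call with another sign, 39 lost it, 29 gained it and 3 reversed. Lists were not rerun with DESeq2, and the pseudocount planned for normalized values was not run because the file holds counts.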

Other observations

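The genes and the cell cycle, neuroblast and wider-rise tests in this part were chosen after the results over all genes were seen, and the splits of the mice were planned.

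Among the 173 lower genes outside the fixed lists were 2 TGF-beta receptor genes, with no list of that pathway tested: Tgfbr1 fell from 18.6 ± 1.11 to 9.13 ± 0.385 CPM (-1.03, SE 0.08, adjusted p = 5.60e-05 in edgeR) and Tgfbr2 from 13.7 ± 0.980 to 9.29 ± 0.648 CPM (-0.55, SE 0.09, adjusted p = 0.0108). Bulk counts do not show whether these receptor transcripts were lost with the microglia or fell in other cells. The macrophage genes Mpeg1 (-3.84) and Pld4 (-5.14) fell too, and the lysosomal genes Grn (-0.36) and Man2b1 (-0.30), which many cell types express, fell slightly. The collagen genes of the vascular basement membrane, Col4a1 (-0.34, SE 0.07, adjusted p = 0.0387) and Col4a2 (-0.41, SE 0.08, adjusted p = 0.0497), fell as well, while no gene of the endothelium or pericyte lists passed in edgeR. In each of these 8 genes, as in every lower gene past the threshold, all 4 depleted mice lay below all 4 control mice.

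The 4 higher genes too weakly expressed for the rule were the mitotic genes Top2a (0.668 ± 0.202 to 2.35 ± 0.840 CPM, 1.81, SE 0.30), Ube2c (1.64, SE 0.28) and Bub1 (2.25, SE 0.42) and the noncoding Gm19569 (1.09). Of 30 further cell cycle genes, 27 had a positive fold change and 0 passed in edgeR, and their median was 0.300. Camera with an estimated correlation gave p = 0.0163 (adjusted p = 0.0651 over the lists added with it). Their score was higher in depleted mice (exact permutation p = 0.0286). The median lies between the bounds set for and against a wider rise. Tissue with neuroblasts taken along with the striatum could bring such genes: with the striatum score as a covariate the list kept 0.812 of its median. That share passes the bound set beforehand against this explanation, but the 95% bootstrap interval over genes, added after the share was seen, runs from 0.505 to 1.30, so the explanation was left open. In addition 13 neuroblast genes had a median of 0.13 (p = 0.138 with an estimated correlation). With that covariate Top2a stood at 1.63 and Bub1 at 1.58, with standard errors of 0.43 and 0.49 in place of 0.30 and 0.42, and neither passed. Tissue content and cycling cells in the depleted forebrain therefore cannot be told apart here.

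Of the 35 splits of the 8 mice into groups of 4, only 1, the real one, called as many as 234 genes (127 at most in any other). That is the smallest share that 35 splits can give. Every other split put depleted and control mice into the same group, which widens the spread within groups. The splits therefore cannot exclude chance for the count as a whole. For the 11 higher genes chance is not excluded either, because 2 of 35 splits reached that number in one direction, with 99 as the highest other. That other split set control mice 1, 3 and 4 and depleted mouse 2, which have the 4 lowest striatum scores, against the rest, and so points to a structure of the samples; with the striatum score as a covariate the real split gave 166 lower and 2 higher genes. For the lists, 4 of 35 splits called as many as the 12 found with the preset correlation, up to 13, so chance is not excluded there, while 1 of 35, the real one, reached the 2 found with an estimated correlation, against 1 at most in any other.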
